A study of Homo sapiens with 6 samples.

How the data were processed

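The series holds 6 arrays of RNA from cultured primary human lung fibroblasts. Per the labels, 3 samples were fibroblasts grown from airway specimens and 3 were fibroblasts grown from distal lung specimens, all taken during bronchoscopy. The labels describe the cells as cultured, while their extraction protocol speaks of RNA from lung tissue, and the RNA kits named for the series and for the samples differ. Each RNA was labelled with Cy3 and hybridised alone to an Agilent Whole Human Genome array.

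Per the file headers, the scanner images were read with Agilent Feature Extraction 9.5.3.1. Spatial detrending and multiplicative detrending were switched on, and the setting named background correction was switched off. The submitters' processing notes name the same program. The values used were the deposited spot intensities on a linear scale: the processed signal of each spot for the main values, and the mean signal with its local background for 1 alternative. No scaling between arrays had been applied to them. The authors' value table of the series held the same processed intensity as the scanner output, since 43376 of 43376 rows were equal on every array to within 1e-04 of the value. Its scale was therefore linear and uncentred, and it differed from the main values only in keeping spots marked as outliers. The median intensity of each array is the same in both.

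Each array held 45015 spots, of which 43376 were not controls. The median processed intensity of these spots was 108.2, 97.5 and 78.9 on airway arrays 1, 2 and 3 and 125.2, 109.7 and 111.2 on distal arrays 1, 2 and 3. The share of spots well above background, by the program's own mark, was 73.5%, 74.1% and 66.2% on the airway arrays and 73.7%, 72.6% and 69.9% on the distal arrays. No spot was saturated. The number of arrays limits the precision of every value.

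Control spots were left out, as were spots marked as non-uniform or as population outliers, and spots of one probe were averaged. Of 41000 probes, 222 had no usable spot left on at least 1 array and were dropped. Y-linked genes, XIST and TSIX were left out of everything. The remaining 40637 probes were named with a table of RefSeq gene names (assembly GRCh38.p14, used for names only): 23438 through the accession in the file, 3892 through a symbol or older symbol in the file, and 13307 kept the name the file gave. Coordinates are those in the files, on hg18, and 40226 probes had them. No genome or annotation of that build was used here, so exons, introns and untranslated regions are not stated.

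The main values were log2 of the processed intensity minus the array's 75th percentile. Probes were kept where they were well above background on at least 3 of the 6 arrays, which left 29451 probes, and the probe with the highest mean stood for its gene. This gave 21685 genes, 14159 of them with a symbol. They were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, distal minus airway, two-sided) with Benjamini-Hochberg adjustment and a threshold of 0.05. Where a gene was not well above background on any array of a site, its fold is given as "at least". It was computed against a mean over the site's arrays. Each array gave the higher of the gene's own value and the lowest value of any probe well above background on it. Genes not well above background can lie above that lowest value. For F3 and FGF9, higher in distal cultures, the folds so computed equal the plain ones, 52.8 and 61.5. The same holds, after rounding, for HOXC9, CILP, GPR4, KY and EFCAB6, higher in airway cultures. For these genes the fold is a plain ratio, so "at least" is not a strict lower bound. Gene lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists, and again with a correlation estimated from the arrays. With an estimated correlation, camera also reads its statistic against the few residual degrees of freedom of the fit. A call lost in that setting need not be due to correlation. The estimate was below 0.01 for the matrix glycoprotein list (0.00123) and the adventitial list (-0.0322), among others. The rotation test fry was run as an alternative. Counts of list members were taken both over all genes tested and adjusted over the list alone. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, and the files were read with pandas 2.3.3.

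The design, the alternatives and 29 gene lists (22 pathways or functions and 7 sets of cell type markers) were fixed before the data were examined. All 29 lists had at least 5 measured members. The rule for named genes, fixed at the same time, had 5 parts. It took up to 12 genes per direction with the largest difference among those past the threshold and in the same direction in all 3 numbered pairs. It filled up first from the fit with the replicate number as a block and then, said not to pass, from genes with a log2 difference of at least 1 in the same direction in all pairs, by smallest unadjusted p. It took only genes with a symbol. In each list it took up to 4 members past either fit over all genes, or otherwise the 2 members with the largest difference, given as values. It also took ACTA2, TAGLN, CNN1, COL1A1, ELN, MAPK8, SOX9, TBX4 and FOXF1 whatever their values. List members named as higher or lower because they passed when adjusted over the list alone, and a pair of probes without a symbol in the closing section, fall outside that rule and were chosen after their values were seen. A few genes that the rule took are not reported here.

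The labels number the samples 1 to 3 at each site. Same-numbered samples of the 2 sites share a code in the labels, whose meaning is not given. They lay on the same slide, scanned together, so the replicate number, the slide and the scan are a single block. The correlation across genes of each array's deviation from its site's mean was 0.248, 0.399 and 0.468 between same-numbered arrays, and between -0.378 and 0.042 for different numbers. The numbers were therefore taken to pair the samples. The main model has no block, and the blocked value is printed beside a result where it changes the call or moves a count by more than 1.5 times. The labels do not state the test that the study used or how many donors there were, so p-values measure the spread between these cultures. In the main model that spread includes the differences between slides, scans and shared codes, which the replicate block takes out. On every slide the airway sample was in position 3 and the distal sample in position 1, so position on the slide and site cannot be told apart.

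Alternatives covered the replicate block, normexp background correction with an offset of 50, quantile normalization, median centring, the authors' value table, no filter on dim probes, a filter asking for all 6 arrays, the mean over a gene's probes, eBayes with trend and robust options, array weights, each array left out in turn, each pair left out in turn with the block, other thresholds, unmoderated tests, and the other list tests. The slide as a block is the same model as the replicate block.

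The steps were tested on simulated data made for the distal against airway comparison, with 21685 genes, of which 200 were changed, in each of 20 simulations. Without the block, the test recovered 0.2% of genes changed by 1 on the log2 scale, 31.2% of those changed by 2, 80.5% of those changed by 4 and 93.6% of those changed by 6, with 1 false call per simulation. With the block these shares were 0.2%, 11.1%, 80.3% and 93.3%, with 4.5 false calls. A list shifted by 0.5 was recovered in 20 of 20 simulations, and 0 of 560 tests of lists that had not been shifted passed. Simulated genes were drawn independently of each other. In the real arrays the estimated correlation within a list ranged from -0.0957 (mesothelial markers) to 0.7 (cholesterol synthesis). The simulations therefore do not show how often a list of correlated genes passes without a shift. Each simulated gene's variance was also drawn without regard to its signal or its change. In the arrays, some genes with large differences varied widely and did not pass, such as ACTG2 (7.53 ± 1.29) and ALDH1A1 (5.89 ± 2.16). The shares recovered need not hold for such genes.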

Results

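Gene expression was measured on 6 one-colour arrays, each hybridised with RNA from 1 culture of primary human lung fibroblasts, the cells that lay down the connective tissue of the lung. In 3 cultures the fibroblasts came from airway specimens and in 3 from distal lung specimens, the part of the lung that holds the alveoli. Each array carried 43376 spots that were not controls. Between 66.2% of them (airway replicate 3) and 74.1% (airway replicate 2) were well above background. Samples with the same number lay on the same slide, with the airway sample always in position 3 and the distal sample always in position 1, so that position and site cannot be told apart. All differences below are log2 intensities relative to the array's 75th percentile, distal minus airway, with their standard error, for 3 arrays per site.

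The first question was which genes differ between fibroblasts of the distal lung and of the airway, the contrast that the series names. The genes higher in distal lung fibroblasts included some used in smooth muscle contraction and the Wnt ligand genes WNT2 and WNT5A, and none of them passed with the replicate block. PPP1R14A, which encodes an inhibitor of myosin phosphatase, was at least 143-fold higher in distal cultures (difference 7.43 ± 0.52, adjusted p = 0.0318, and 0.0731 with the block). TAGLN, which encodes the actin-binding smooth muscle protein transgelin, was 8.78-fold higher (3.13 ± 0.32, adjusted p = 0.0488, and 0.104 with the block). The oxytocin receptor gene OXTR was 30.4-fold higher on its brightest probe (4.92 ± 0.44, adjusted p = 0.0415, and 0.092 with the block), while its other probe, well above background on all 6 arrays, differed by 2.49. WNT2, which encodes a secreted Wnt ligand, was at least 68.7-fold higher (6.34 ± 0.61, adjusted p = 0.0442, and 0.0731 with the block), and the related ligand gene WNT5A was 8.57-fold higher (3.1 ± 0.30, adjusted p = 0.0442, and 0.0731 with the block). After normexp background correction these 5 genes did not pass either, with differences of 2.54 for PPP1R14A, 2.99 for TAGLN, 3.12 for OXTR, 1.54 for WNT2 and 2.31 for WNT5A.

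The other named genes past the threshold in that direction were VAT1L at 8.09 ± 0.74 (at least 245-fold), the ion exchanger gene SLC24A3 at 7.17 ± 0.46 (at least 111-fold) and the transcription cofactor gene DACH2 at 6.01 ± 0.48 (at least 54.9-fold). F3, which encodes tissue factor, the starter of coagulation, differed by 5.72 ± 0.47 (at least 52.8-fold). DUSP27 differed by 4.22 ± 0.39 (at least 15.4-fold), and the tight junction gene CLDN1, well above background on 1 of 3 airway arrays, by 4.91 ± 0.51. The junctophilin gene JPH2 differed by 3.91 ± 0.38 on its brightest probe but by 0.68 and 0.29 on its other 2 probes, and it did not pass with the mean over its probes (1.63, adjusted p = 0.16), and the second probe of SLC24A3, not well above background on any array, differed by 1.02. With the replicate block the adjusted p of these 7 genes was 0.0731 (SLC24A3, CLDN1 and DUSP27) to 0.101 (JPH2). After normexp background correction they did not pass, with differences from 0.71 (DUSP27) to 2.56 (VAT1L).

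Few named genes passed the threshold in the other direction. TLR4, the receptor for bacterial lipopolysaccharide, was 18.3-fold higher in airway cultures (difference -4.20 ± 0.38, adjusted p = 0.0415, and 0.0731 with the replicate block). ECM2, a gene for an extracellular matrix protein, differed by -2.46 ± 0.24 (adjusted p = 0.0442, and 0.0824 with the block). HOXC9, a homeobox gene, was at least 9.8-fold higher in airway cultures (-3.29 ± 0.29, adjusted p = 0.0415, and 0.0731 with the block). It lay near the background, and after normexp background correction, under which all genes shifted by a median of 0.143, its difference was 0.098, or -0.045 relative to that shift. TLR4 and ECM2 were then at -1.22 and -1.81 and did not pass. Further genes that the rule named did not pass. GCNT1 differed by -2.52 ± 0.27 (adjusted p = 0.0548, and 0.0476 with the mean over a gene's probes), and the others given here had an adjusted p of 0.0763. They were the chemokine-scavenging receptor gene ACKR4 at -7.07 ± 0.90, the cartilage matrix gene CILP at -4.66 ± 0.58 (at least 25.4-fold), GPR4 at -3.84 ± 0.49 (at least 14.3-fold), KY at -3.41 ± 0.42 (at least 10.6-fold), GPNMB at -3.35 ± 0.42, the scavenger receptor gene COLEC12 at -3.07 ± 0.39 and EFCAB6 at -2.51 ± 0.32 (at least 5.71-fold). Under normexp the differences of the dim genes among these all but vanished, at -0.004 for KY, -0.051 for GPR4 and 0.194 for EFCAB6, or -0.147, -0.194 and 0.051 relative to the shift, while CILP was at -0.98.

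**Figure D1:**
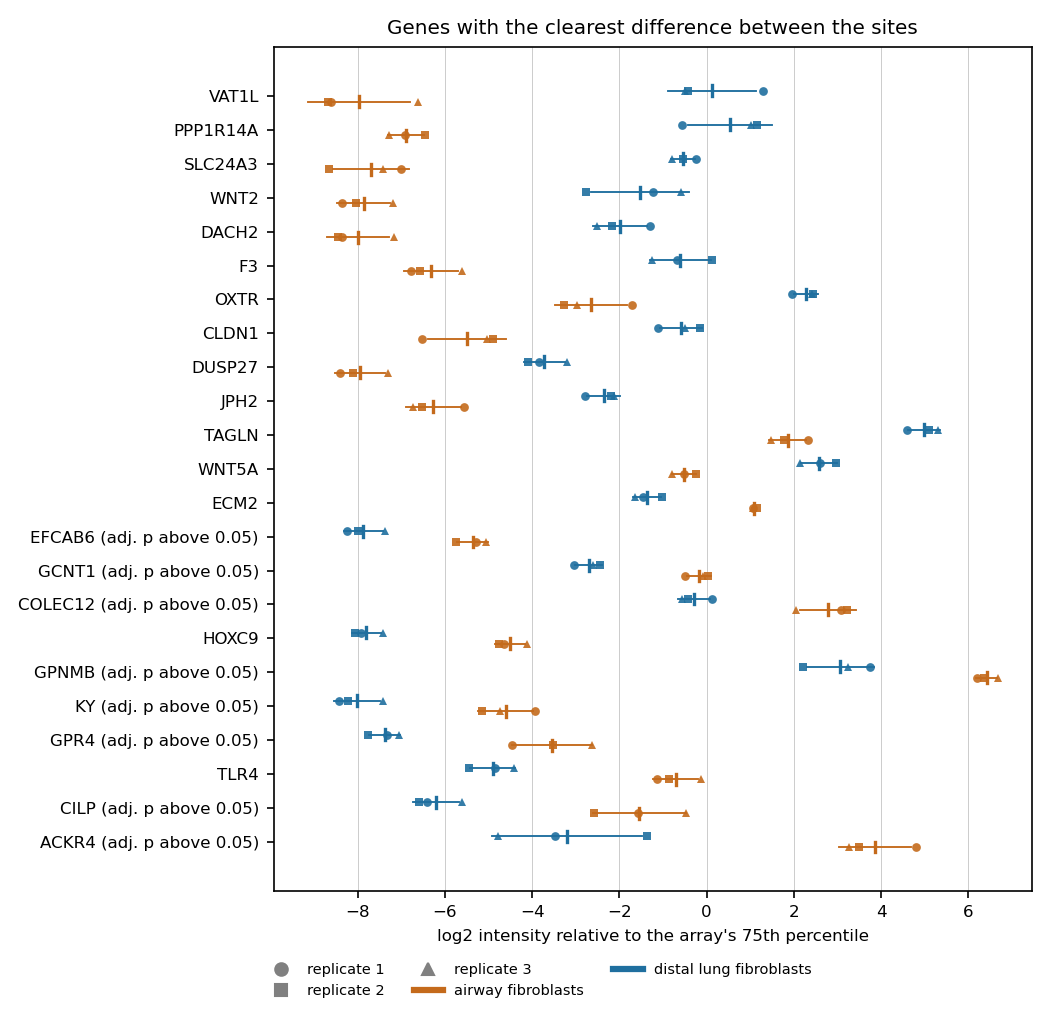
Log2 intensity relative to the array's 75th percentile (x axis) of genes that the naming rule took for the single-gene comparison, for airway (orange) and distal lung (blue) fibroblasts; symbols mark replicates 1 to 3, short vertical bars the mean and horizontal bars the SD (n = 3). For TAGLN, all 3 distal arrays lie above all 3 airway arrays, with means of 4.99 and 1.86; relative to the shift of all genes under normexp, the differences of HOXC9, KY, GPR4 and EFCAB6 were -0.045, -0.147, -0.194 and 0.051, the last with its sign turned.

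In all, 24 of 21685 genes passed limma's test, 21 higher in distal and 3 higher in airway cultures, each in the same direction on all 3 slides. Of these 24, 15 carry a symbol and are named above. At an unadjusted p below 0.05 there were 2000 genes, where chance gives 1084. Among the other splits of the 6 arrays into 3 and 3, those that part all 3 numbered pairs, as the real one does, gave 444, 210 and 312, and those that part 1 pair gave up to 2353. With the replicate number as a block, 0 genes passed limma's test (smallest adjusted p 0.0731, 2861 genes at an unadjusted p below 0.05), and the unmoderated test also gave 0. Of the 24 genes, 21 had an adjusted p below 0.1 with the block. The count also fell to 0 with normexp background correction or a filter asking for signal on all 6 arrays and to 4 with no filter, and rose to 148 with array weights. It was 4, 1 and 40 without airway replicate 1, 2 or 3, and 1, 0 and 0 without distal replicate 1, 2 or 3.

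The genes' positions on hg18 are those of their probes. VAT1L was measured on chromosome 16 from 76571136 to 76571195, SLC24A3 on chromosome 20 from 19651459 to 19651518, WNT2 on chromosome 7 from 116704621 to 116704680, OXTR on chromosome 3 from 8769082 to 8769141, TAGLN on chromosome 11 from 116580365 to 116580424, WNT5A on chromosome 3 from 55476693 to 55476752, TLR4 on chromosome 9 from 119519057 to 119519116 and HOXC9 on chromosome 12 from 52682879 to 52682938.

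The second question was which of the gene lists fixed in advance differed as a group. The list of smooth muscle and myofibroblast contractile genes was higher in distal cultures. Of its 22 measured members 21 lay above 0, 19 of them in all 3 pairs, with a median difference of 1.28. TAGLN passed over all genes, and 12 members were higher and 0 lower when adjusted over the list alone. The largest differences were those of the actin gene ACTG2 at 7.53 ± 1.29, SYNPO2 at 6.35 ± 0.96 and the smooth muscle myosin gene MYH11 at 6.18 ± 0.99, followed by CNN1, which encodes calponin, at 4.12 ± 1.08 and the intermediate filament gene DES at 3.31 ± 0.98. ACTA2, which encodes smooth muscle actin and is the usual marker of myofibroblasts, differed by 0.89 ± 0.33 and did not pass when adjusted over the list alone (adjusted p = 0.0612, and 0.0435 with the replicate block). Camera's adjusted p for the list was 3.01e-17 with the preset correlation, and the call was lost with an estimated one (adjusted p = 0.0757 with an estimated correlation). The median was 1.44, 1.51 and 1.41 within slides 1, 2 and 3.

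The markers of pericytes and vascular smooth muscle, some of them shared with that list, were also higher in distal cultures, with a median difference of 2.90 over 12 measured members and 6 higher when adjusted over the list alone (adjusted p = 5.1e-05, and adjusted p = 0.148 with an estimated correlation). Its members that passed were the shared genes ACTG2, MYH11, DES and LMOD1 (2.41 ± 0.47), the adhesion molecule gene MCAM (4.74 ± 0.82) and PLN, the gene for the calcium pump regulator phospholamban (3.75 ± 1.02, at least 10.4-fold). The median was 2.72, 1.80 and 2.0 within slides 1, 2 and 3, and 1.74 without airway replicate 1. It was 0.41 with no filter on dim probes and 0.38 with a filter asking for signal on all 6 arrays, and 1.18 after normexp background correction. Genes of actin binding and cytoskeletal organisation were higher as a group by a small amount, with a median of 0.36 over 39 members and 27 above 0 (adjusted p = 0.00318, and adjusted p = 0.148 with an estimated correlation). None of the 39 passed alone, and the list's call was lost after normexp background correction (adjusted p = 0.106) and with the block and pair 2 left out (median 0.35, adjusted p = 0.261). Its largest differences were -2.91 ± 1.77 for SORBS2 and 1.39 ± 0.56 for DIAPH3. The SORBS2 value came mostly from airway replicate 1, since the differences in pairs 1, 2 and 3 were -7.76, -0.75 and -0.21.

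Genes of matrix glycoproteins and proteoglycans were higher in airway cultures as a group. Of 54 measured members 37 lay below 0 and the median difference was -0.46. Adjusted over the list alone, 10 were lower and 4 higher in distal cultures. ECM2 passed over all genes. HAPLN1, which encodes a link protein of the hyaluronan matrix, differed by -7.07 ± 1.64, the microfibril gene MFAP5 by -6.53 ± 0.99, the small proteoglycan gene OGN by -5.52 ± 0.74, and VIT by -5.24 ± 1.34. Members that were higher in distal cultures included NPNT, which encodes the integrin ligand nephronectin, at 4.15 ± 0.82 (at least 14.7-fold). ELN, the elastin gene, differed by 0.84 ± 0.63 and did not pass. Camera's adjusted p was 0.00101, and the call was lost with an estimated correlation (adjusted p = 0.105 with an estimated correlation). The median was -0.05, -0.72 and -0.56 within slides 1, 2 and 3. The members lower and higher, 10 and 4 in all, numbered 6 and 1 without airway replicate 2 and 5 and 0, 5 and 1, and 6 and 2 without distal replicate 1, 2 and 3. They were 3 and 1 after normexp background correction, and 17 and 4 with the block and pair 1 left out.

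**Figure D2:**
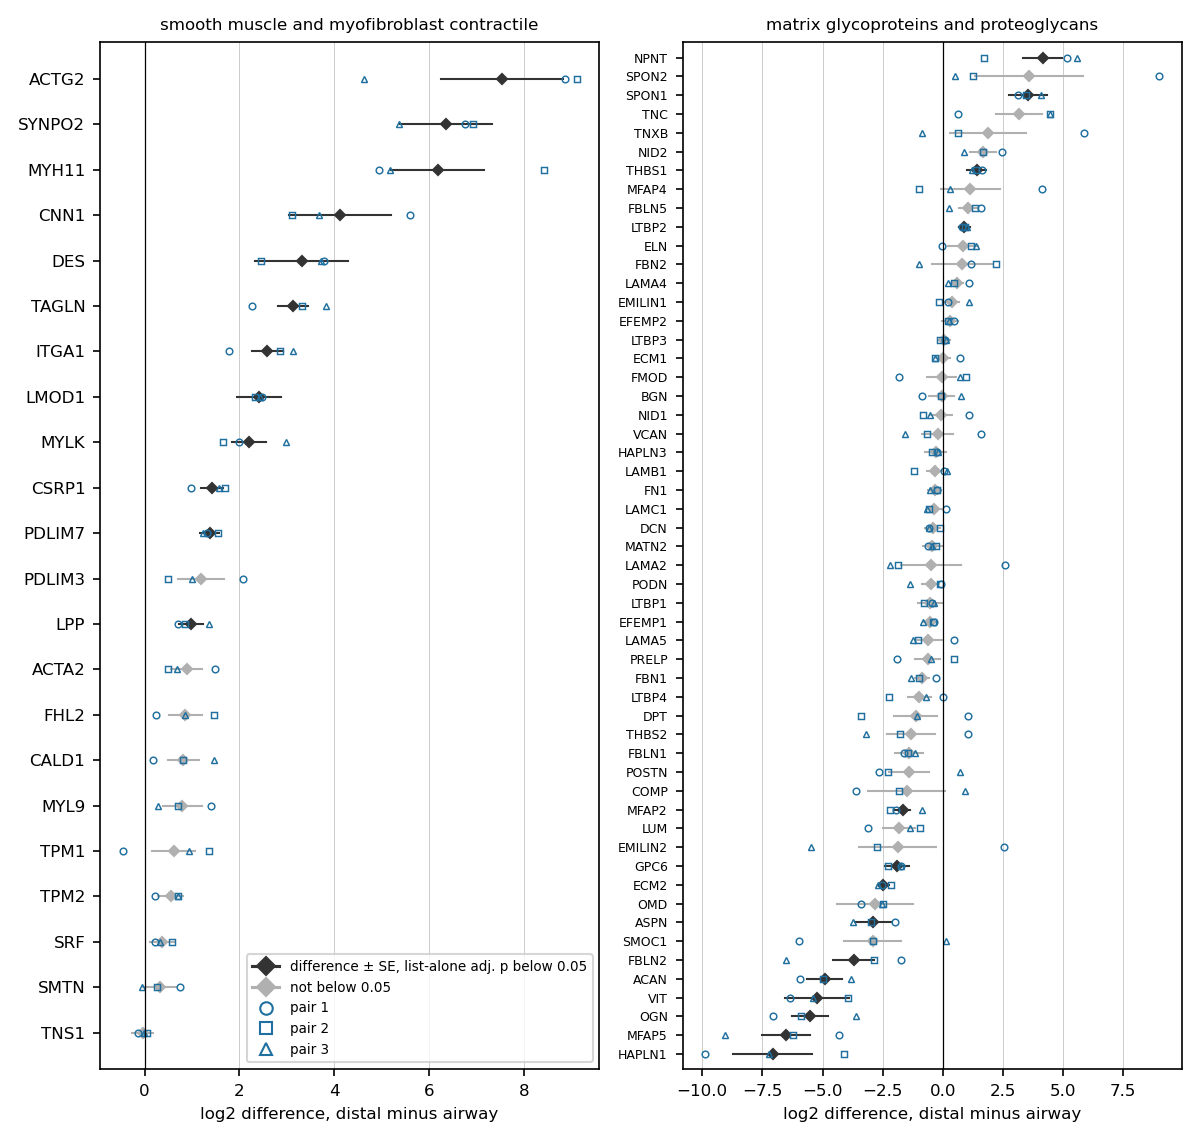
Log2 difference, distal minus airway (x axis), of every measured member of the contractile list (left, 22 genes) and of the matrix glycoprotein and proteoglycan list (right, 54 genes); diamonds and bars are the difference ± SE over 3 arrays per site, dark where the adjusted p over the list alone was below 0.05, and open symbols are the 3 numbered pairs. On the left 21 of 22 genes lie above 0, and on the right 37 of 54 lie below 0.

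The other matrix lists did not pass as groups. Collagens had a median of 0.61 over 25 members (adjusted p = 0.508), and COL1A1, the main fibrillar collagen gene, differed by -0.02 ± 0.55. The basement membrane collagen genes COL4A6 (6.65 ± 1.06) and COL4A5 (3.89 ± 0.85) were higher when adjusted over the list alone. The other probes of COL4A5 differed by 1.85 and 2.48 and that of COL4A6 by 2.57, and with the mean over a gene's probes 1 collagen was higher. With the replicate block the adjusted p of both genes over the list was 0.0646 each and a single collagen passed, lower in distal cultures. The 2 collagens higher over the list alone became 5 without airway replicate 1, 1 with 1 lower without airway replicate 3 or distal replicate 1, 1 without distal replicate 3, and 0 without airway replicate 2 or distal replicate 2. Genes of matrix crosslinking and proteolysis had a median of -0.05, a mean of 0.12 and a test direction toward airway (adjusted p = 0.768). Their largest differences were 3.74 ± 1.32 for the protease gene MMP3 and -3.46 ± 1.01 for PCOLCE2, and 0 members passed over the list alone, against 2 higher and 3 lower with the replicate block. Cartilage markers had a median of -0.12 over 15 members (adjusted p = 0.512), with ACAN, the gene for the cartilage proteoglycan aggrecan, at -4.91 ± 0.71 and the shared gene HAPLN1 lower and MATN3 higher (2.81 ± 0.51, at least 5.59-fold) over the list alone. The 2 lower were 1 without airway replicate 1 or 2 or distal replicate 1 or 3, and the 1 higher was 2 without airway replicate 3 and 3 with the replicate block. SOX9, the transcription factor gene of cartilage, differed by -0.42 ± 0.58.

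Markers of fibroblast subtypes moved apart. The list of adventitial and airway fibroblast genes was higher in airway cultures, with a median of -1.22 and 18 of 22 members below 0 (adjusted p = 4.79e-06, and adjusted p = 0.0757 with an estimated correlation). The median was -0.72, -1.31 and -1.18 within slides 1, 2 and 3. Adjusted over the list alone, only MFAP5 passed, against 5 members with the replicate block. That 1 was 7 lower and 1 higher without airway replicate 1, 2 without distal replicate 2 or with the mean over a gene's probes, and 0 without distal replicate 3 or after normexp background correction, and the list median was -0.61 after that correction. In the same list the complement gene CFD differed by -3.70 ± 1.68. Alveolar fibroblast and lipofibroblast genes were higher in distal cultures, with a median of 0.45 over 25 members (adjusted p = 0.0259, and adjusted p = 0.794 with an estimated correlation). WNT2 and NPNT were higher over the list alone, 4 members were higher and 1 lower with the replicate block, 3 were higher without airway replicate 2, 1 was without distal replicate 1 or 3, and 0 were after normexp background correction. The alveolar list's call did not hold with the block (adjusted p = 0.057), with a filter asking for signal on all 6 arrays (adjusted p = 0.122), without airway replicate 1 (median 0.20, adjusted p = 0.984, with 2 members higher and 4 lower over the list alone), without distal replicate 3 (adjusted p = 0.067) or with the block and pair 1 left out (adjusted p = 0.585), and its median was 1.41, 0.28 and 0.25 within slides 1, 2 and 3. General fibroblast markers were higher in airway cultures, with a median of -0.42 and 13 of 15 members below 0 (adjusted p = 0.00477, and adjusted p = 0.148 with an estimated correlation). S100A4, a calcium-binding protein gene, was lower in distal cultures over the list alone (-2.49 ± 0.49), though 0 members were without airway replicate 2 or 3 or any of the distal replicates, against 2 with the replicate block, and the proteoglycan gene LUM differed by -1.80 ± 0.67. The medians within slides 1, 2 and 3 were -0.08, -0.37 and -0.97, and the call did not hold with array weights (adjusted p = 0.0672), without distal replicate 3 (median -0.25, adjusted p = 0.0552) or with the block and pair 3 left out (median -0.28, adjusted p = 0.103).

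Lists of developmental genes did not pass as groups but held large single differences. Wnt signalling genes had a median of 0.12 over 42 members (adjusted p = 0.512), with 5 higher and 3 lower over the list alone. Besides WNT2 and WNT5A these included the Wnt inhibitor genes APCDD1 at 6.05 ± 1.0 and FRZB at 2.40 ± 0.34, the transcription factor gene TCF7 at -1.91 ± 0.44 and the receptor gene FZD4 at -1.68 ± 0.31. After normexp background correction 2 Wnt genes were higher and 1 lower over the list alone. The Wnt list's median was -0.049 with array weights. Lung mesenchyme patterning factors had a median of 0.22 over 49 members (adjusted p = 0.564). TBX4, a transcription factor gene of embryonic lung mesenchyme, differed by 5.87 ± 0.89 (adjusted p = 0.1003 over all genes) and was higher over the list alone, as were NR2F1 at 2.80 ± 0.44 and FOXF2 at 1.85 ± 0.41, while FOXC1 at -2.93 ± 0.67 and PRRX1 at -1.53 ± 0.30 were lower. The other probes of FOXC1 differed by -2.68 and 0.18, both well above background on all 6 arrays, and with the mean over a gene's probes 1 factor was lower. These 3 higher and 2 lower factors were 5 and 5 without airway replicate 3, 2 and 1 without airway replicate 2 or distal replicate 3, 3 and 1 without airway replicate 1, 3 and 0 without distal replicate 2, and 0 and 0 without distal replicate 1. They were 1 and 0 after normexp background correction, and the list's median was 0.065 without airway replicate 1. FOXF1 differed by 1.75 ± 0.50 and PITX1 by 4.14 ± 1.5, neither past the test.

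HOX genes had a median of 0.25 over 17 members (adjusted p = 0.512), with HOXC9 lower and HOXB5 higher (1.19 ± 0.27) over the list alone, the latter not so without airway replicate 1 or 3 or distal replicate 1 or 3. The HOX list passed with a filter asking for signal on all 6 arrays (median 0.39, adjusted p = 0.0437), and its median was -0.44, 0.17 and 1.03 within slides 1, 2 and 3. Genes of TGF-beta and BMP signalling had a median of -0.01, a mean of 0.20 and a test direction toward distal (adjusted p = 0.725), and the largest differences were those of the BMP inhibitor gene CHRDL1 (1.88 ± 0.59) and of TGFBI (1.43 ± 0.47). Retinoid genes had a median of 0.23 over 18 members (adjusted p = 0.442), with ALDH1A1, which makes retinoic acid, at 5.89 ± 2.16 and the retinol carrier gene RBP4 at -5.28 ± 1.25, neither of which passed. With the mean over a gene's probes 2 retinoid genes were higher and 1 lower over the list alone. The retinoid list's median was 0.78 without airway replicate 3 and 0.54 without distal replicate 2, and the list passed with the block and pair 2 left out (median 0.49, adjusted p = 0.0309, 6 higher and 1 lower).

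Growth factors and their receptors were higher in distal cultures, with a median of 0.41 and 40 of 59 members above 0 (adjusted p = 0.00173, and adjusted p = 0.148 with an estimated correlation). Over the list alone 8 were higher and 0 lower. FGF9 differed by 5.94 ± 0.81 (at least 61.5-fold), the IGF-binding protein genes IGFBP5 and IGFBP2 by 3.22 ± 0.43 and 3.08 ± 0.54, IGF1 by 2.99 ± 0.48 and the ephrin gene EFNB2 by 2.60 ± 0.32. The median was 0.72, 0.54 and 0.16 within slides 1, 2 and 3, and 14 members were higher without airway replicate 3, while 4 were after normexp background correction and 0 with the block and pair 2 left out. Integrins and other adhesion genes had a median of 0.38 over 39 members, with 27 above 0 (adjusted p = 0.0193, and adjusted p = 0.148 with an estimated correlation). MCAM, the collagen-binding integrin gene ITGA1 (2.59 ± 0.32) and the cadherin gene CDH4 (2.50 ± 0.37) were higher over the list alone, while CADM1 differed by 3.97 ± 2.11. The list's call did not hold with the replicate block (adjusted p = 0.057), without distal replicate 3 (adjusted p = 0.0552) or with the block and pair 2 or 3 left out (adjusted p = 0.122 and 0.0589), and its median was 0.11, 0.29 and 0.16 within slides 1, 2 and 3. The 3 adhesion genes were 8, with 1 lower, without airway replicate 1 and 5 without airway replicate 2 or with the mean over a gene's probes, against 0 after normexp background correction, and 7 (with 1 lower), 0 and 1 with the block and pair 1, 2 or 3 left out.

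Cytokines, chemokines and prostaglandin enzymes had a median of -0.04, a mean of 0.38 and a test direction toward distal (adjusted p = 0.542). The monocyte attractant gene CCL2 was higher (2.82 ± 0.45) and the prostacyclin synthase gene PTGIS lower (-3.68 ± 0.64) over the list alone. The other probe of PTGIS, well above background on all 6 arrays, differed by -0.82, and with the mean over a gene's probes 0 members were lower. In this list 3 were higher and 0 lower with the replicate block, 2 and 2 without airway replicate 1, 0 and 1 without airway replicate 2 and 0 and 0 without distal replicate 1 or 3, and the adhesion receptor gene VCAM1 differed by 4.91 ± 1.49. The cytokine list passed without airway replicate 3 (median 0.41, adjusted p = 0.0196, 5 members higher and 1 lower) and after normexp background correction (median 0.34, adjusted p = 0.0109). In the list of JNK and AP-1 genes (median -0.05 over 28 members, adjusted p = 0.564) the kinase gene MAP3K1 was higher (1.84 ± 0.20) and ATF3 lower (-1.41 ± 0.25) over the list alone, while 0 were lower with the block or without airway replicate 1 or 2 or distal replicate 1 or 2, and MAPK8, which encodes JNK1, differed by 0.37 ± 0.20 (adjusted p = 0.722), and by -0.23 and 0.76 on its other probes. Interferon-stimulated genes had a median of -0.06 over 37 members (adjusted p = 0.564). Of these, GBP1 (1.34 ± 0.22) was higher over the list alone, and 0 were without airway replicate 1 or 2 or any of the distal replicates, while with the replicate block 2 were higher and 3 lower, among them USP18 (2.58 ± 0.80) and OAS1 (-2.10 ± 0.81). The interferon list passed toward airway without airway replicate 1 (median -0.38, adjusted p = 0.0114) and toward distal without airway replicate 3 (median 0.26, adjusted p = 0.0324), and toward airway with the block and pair 1 left out (median -0.26, adjusted p = 0.000318). Complement and antigen presentation genes had a median of -0.06 over 22 members (adjusted p = 0.508), with CFD and CFI (3.65 ± 1.22) furthest from 0, and 0 passed over the list alone, against 1 higher and 1 lower with the replicate block. The complement list passed without airway replicate 2 (median -0.18, adjusted p = 0.0461) and after normexp background correction (median -0.11, adjusted p = 0.0277).

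Cell cycle genes were higher in distal cultures, with a median of 0.53 and 41 of 45 members above 0. Camera's adjusted p was 9.1e-08, and the call was lost with an estimated correlation (adjusted p = 0.213 with an estimated correlation). The mitotic kinase gene AURKA differed by 2.34 ± 0.53, DLGAP5 by 2.19 ± 0.55 and the topoisomerase gene TOP2A by 1.91 ± 0.33, all higher over the list alone, and the cyclin gene CCND2 by 2.22 ± 0.93. Over the list alone 7 were higher and 0 lower, against 12 with the replicate block. That 7 was 0 without airway replicate 1, airway replicate 2 or distal replicate 2, 1 without distal replicate 1, and 2 without distal replicate 3, and 0 with quantile normalisation, after normexp background correction, and with the block and pair 2 or 3 left out. After normexp the median was 0.28, or 0.14 relative to the shift of all genes. The median was 0.51, 0.85 and 0.24 within slides 1, 2 and 3, and 0.33 without distal replicate 2.

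The metabolic and stress lists did not pass. Cholesterol synthesis genes had a median of 0.36 over 25 members (adjusted p = 0.3), with STARD4 at 1.09 ± 0.61. Genes of hypoxia and glycolysis had a median of -0.02 over 30 members (adjusted p = 0.512), with CA12 at -3.30 ± 1.0 and ANKRD37 at -1.26 ± 0.62. Genes of the unfolded protein response and amino acid stress had a median of 0.27 over 24 members (adjusted p = 0.564), with SLC3A2 at -1.14 ± 0.29 and TRIB3 at -0.82 ± 0.35. Without airway replicate 3, the array with the lowest share of spots above background, the cholesterol list (median 0.57, adjusted p = 0.00376) and the unfolded protein list (median 0.68, adjusted p = 0.000672, 3 members higher over the list alone) both passed, as they did with the block and pair 3 left out (medians 0.69 and 0.68, adjusted p = 0.000129 and 0.00151) and with array weights (0.49 and 0.55, adjusted p = 0.0261 and 0.0266). The hypoxia list passed after normexp background correction (median -0.15, adjusted p = 0.0287).

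Besides the pericyte and vascular smooth muscle list, which passed, and the cartilage list, which did not, 4 lists held markers of other cell types that a culture could hold, and these did not pass. The median was 0.14 for epithelial markers (19 members, adjusted p = 0.639), 0.22 for endothelial markers (9 members, adjusted p = 0.768), 0.07 for leukocyte markers (9 members, adjusted p = 0.818) and -0.02 for mesothelial markers (8 members, adjusted p = 0.564). The largest single differences were 3.55 ± 1.33 for EPCAM and -1.73 ± 0.75 for ABCA3 among epithelial markers, -1.18 ± 0.61 for ROBO4 and 1.11 ± 0.27 for TEK among endothelial markers, 2.48 ± 1.13 for SRGN and -1.05 ± 0.55 for CD68 among leukocyte markers, and -2.43 ± 1.01 for C3 and 1.70 ± 1.09 for KRT19 among mesothelial markers. None of these genes passed over its list alone, while with the replicate block 1 mesothelial marker was higher.

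**Figure D3:**
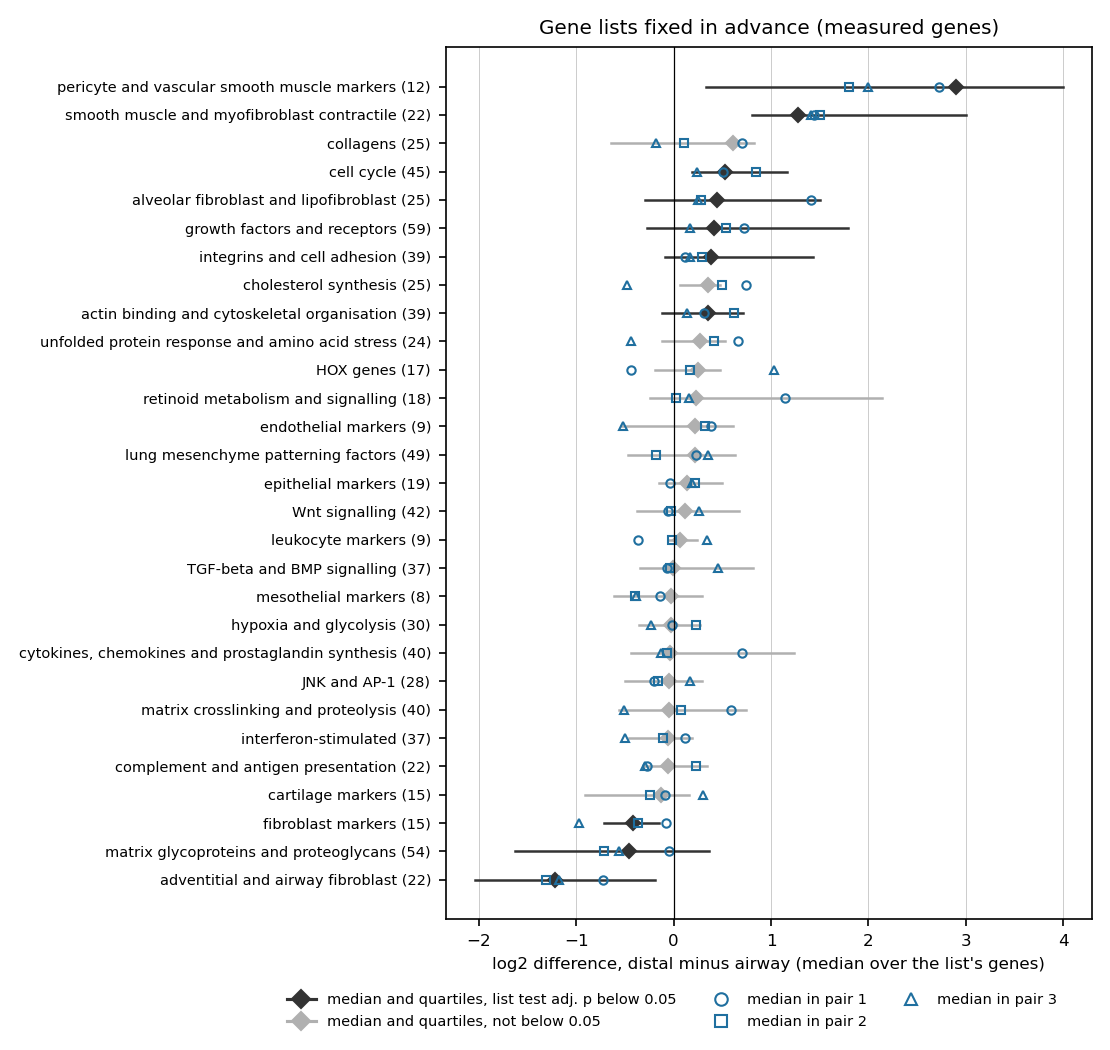
Median log2 difference, distal minus airway (x axis), of each of the 29 gene lists with the number of measured genes in brackets; diamonds are the median over all arrays with bars from the lower to the upper quartile of genes, dark where camera's adjusted p was below 0.05 with the preset correlation, and open symbols are the medians within the 3 numbered pairs. The contractile list lies at 1.28 and the adventitial and airway fibroblast list at -1.22.

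In all, 10 of 29 lists passed camera's test with the preset correlation of 0.01, 7 higher in distal and 3 higher in airway cultures. The other splits of the arrays that part all 3 numbered pairs gave 13, 1 and 13 lists, and those that part 1 pair gave up to 5. With the estimated correlation 0 passed camera, 8 lists had an unadjusted p below 0.05, and fry called 10, or 3 with the replicate block. With the replicate block 8 passed, 5 and 3.

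The last comparison asked how far the arrays resembled each other by site and by number. Site accounted for 31.4% of the sum of squares over all genes and replicate number for 46.9%, where 20% and 40% are expected if neither mattered. Across genes, which are not independent replicates, the correlation was 0.952 to 0.975 among distal arrays and 0.921 to 0.955 among airway arrays. Between sites it was 0.941 to 0.953 for the same number and 0.914 to 0.948 for different numbers.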

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

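The alternatives chosen after the data were examined were the blocked fry and the blocked camera with an estimated correlation, the blocked test read against the unblocked degrees of freedom, the contractile list without shared members, and list-alone counts without airway replicate 3. The count of 24 genes stayed within 1.5 times under quantile normalisation (30), median centring (19), the authors' value table (24), the mean over probes (34) and eBayes with trend and robust options (21). It was 0 with the replicate block, with normexp, with signal asked for on all 6 arrays, in the unmoderated test with and without the block, and with the block and pair 1, 2 or 3 left out, where unadjusted counts were 2861, 520, 1708, 2116, 1887, 2134, 1817 and 3095. It was 4 with no filter (30280 genes tested), 148 with array weights, 94 at an adjusted p below 0.1, 547 with the blocked test read against the unblocked degrees of freedom, and 0 to 40 with 1 array left out. The cause of these changes was not tested apart from the degrees of freedom, where the test cannot settle it. Of 29 lists, 10 passed, against 8 with the replicate block, which took the alveolar and integrin lists and changed no other list's call; none of the named genes kept its call with the block. The list count was 7 to 14 with 1 array left out and 8 to 12 in the other settings of camera at the preset correlation. It was 0 with camera's estimated correlation without and with the block (8 and 4 unadjusted), 10 and 16 with fry for 1 or either direction, and 3 and 23 with fry and the block. The mean correlation of deviations between same-numbered arrays was 0.372, and 0.325 to 0.407 in other settings. The contractile list without the members shared with the pericyte list (18 left) kept a median of 0.93, with 8 higher over the list alone and a p of 0.00372 with an estimated correlation, unadjusted. Signal over background limits the folds given as "at least", since the gene was then not well above background at 1 site. They are not strict lower bounds. The offset of 50 after normexp shrinks the differences of dim probes by construction.

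For the other lists and named genes, 44 list results and 10 gene results turned direction, 201 gene results and 14 list results lost their call, 37 and 15 gained one, and 1785 and 479 kept direction and call. For lists the turn is that of the list test, with the median over members as value, and none of the lists concerned passed in the main test. Under normexp, which shifted all genes by a median of 0.143, collagens were at 0.250, the unfolded protein response at 0.154, mesothelial markers at 0.249, HOXC9 at 0.098, EFCAB6 at 0.194 and ROBO4 at 0.111; relative to the shift these were 0.107, 0.011, 0.106, -0.045, 0.051 and -0.032, so that HOXC9 and ROBO4 kept their sign. Under quantile normalisation matrix crosslinking was at -0.031 and leukocyte markers at -0.117. Endothelial markers were at 0.004 with no filter, and epithelial markers at -0.046 with signal on all 6 arrays. With array weights crosslinking was at 0.099, HOX genes at -0.057, interferon genes at 0.048 and COL1A1 at 0.414. With the replicate block and pair 1 left out, cytokines were at -0.122, cholesterol synthesis at -0.037, the unfolded protein response at -0.057, endothelial markers at 0.197 and SOX9 at 0.212. Without pair 2, crosslinking was at 0.165, endothelial markers at 0.199 and leukocyte markers at 0.067. Without pair 3, crosslinking was at 0.261, TGF-beta genes at 0.037, HOX genes at -0.284, patterning factors at 0.078, interferon genes at 0.113, complement genes at -0.044, hypoxia genes at 0.176, epithelial markers at 0.020, leukocyte markers at 0.042 and COL1A1 at 0.724. With 1 array left out, the range was -0.420 to 0.412 for cytokines, -0.131 to 0.570 for cholesterol synthesis, 0.010 to 0.680 for the unfolded protein response, -0.026 to 0.266 for endothelial markers, -0.094 to 0.202 for leukocyte markers, -0.304 to 0.147 for crosslinking, 0.025 to 0.122 for TGF-beta genes, -0.025 to 0.536 for HOX genes, -0.375 to 0.257 for interferon genes, -0.184 to 0.005 for complement genes, -0.118 to 0.124 for hypoxia genes, 0.251 to 0.591 for collagens, -1.041 to 0.074 for SOX9 and -0.537 to 0.359 for COL1A1. With array weights, counts over the list alone were 15 higher and 1 lower for growth factors, 5 and 2 for integrins, 4 and 1 for cytokines and 4 and 0 for crosslinking. With eBayes trend and robust options they were 5 and 2 for integrins, 0 and 3 for adventitial and 4 and 0 for cell cycle genes. The cause was not tested.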

Other observations

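The tests of pericyte genes, of smooth muscle genes and of a single pair were chosen only after their results had been seen, and the test of degrees of freedom after the blocked count had been seen.

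Of the 24 genes past the threshold, 9 carry no symbol and were left out of the named genes. A probe without a symbol on chromosome 3 from 55477092 to 55477151 (hg18) was higher in distal cultures by 2.94 (adjusted p = 0.0442). It lies 399 bp from the probe of WNT5A, which differed by 3.1 and is on the other strand. Another, on chromosome 16 from 67426714 to 67426773, was higher by 4.54 (at least 19.2-fold, adjusted p = 0.0318). It overlaps on the other strand the probe of the epithelial cadherin gene CDH1, which was well above background on 1 array and differed by 0.13. Both probes were chosen after their values were seen.

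Airway cultures varied more among themselves than distal cultures did: 64.9% of genes had the larger SD among airway arrays, with a median SD of 0.431 against 0.32. Airway replicate 3 had the lowest share of spots above background (66.2%), the lowest array weight (0.334) and a value of 98.73 on the second principal component, which carried 28.6% of the variance. On the first component, which carried 37.6%, airway replicates 1, 2 and 3 were at -97.69, -67.09 and 50.72. Distal replicates 1, 2 and 3 were there at 18.28, 12.9 and 82.88.

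The contractile list stood at a median of 1.28 in distal minus airway cultures. A shift of all probes of like signal, as from position on the slide, would move matched random lists. Of 10000 such lists, 100% had a median below that of the contractile list. An upper quantile of their medians was 0.182, which some of them exceeded. The random lists held genes drawn separately, while the estimated correlation within the contractile list was 0.0697. A median over correlated genes can stray further, so the 100% does not measure chance for such a list. Other effects of position stay open. Pericytes in the distal cultures stay open: the 8 pericyte and vascular smooth muscle markers outside the contractile list had a median of 1.449 (1.655, 0.263 and 0.625 in pairs 1, 2 and 3) but went both ways, from 4.74 for MCAM to -0.91 for CSPG4, with RGS5 at 0.20. Smooth muscle cells also remain a candidate source, and 4 of 4 smooth muscle genes (MYH11, DES, ACTG2 and LMOD1) were higher in all 3 pairs. These genes belong to the contractile list and were chosen after their values were seen, so the count restates the pattern. A rise of the same genes within fibroblasts gives the same count. A difference between fibroblasts of the 2 sites remains open as well.

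The cell cycle list stood at a median of 0.53. The median was above 0 in every pair, the lowest at 0.24 and the highest at 0.85. This was asked after the values were seen and does not show that no pair weighed more. The 7 members higher over the list alone fell to 0 without airway replicate 1, where the list's median was 0.55. Of 10000 matched random lists, 100% had a median below that of the cell cycle list. An upper quantile of their medians was 0.172, which some of them exceeded. The random lists held genes drawn separately, while the estimated correlation within the cell cycle list was 0.153. A median over correlated genes can stray further, so the 100% does not measure chance for such a list. After normexp, though, the cell cycle list was at 0.139 relative to the shift of all genes. Culture conditions such as passage or density are not given in the sources used here and may differ between the sites; they were not tested, nor was a difference between the fibroblasts of the 2 sites.

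With the replicate block 0 genes passed limma's test (2861 at an unadjusted p below 0.05), although the standard error was smaller for 91.7% of genes (median 0.226 against 0.327). Fewer residual degrees of freedom, 2 against 4, are a candidate cause. Read against the unblocked degrees of freedom, the blocked test gave 547 genes, among them all 24. Such a reading can never lower the count, so it cannot settle the cause. In the simulations the blocked fit recovered 80.3% of genes changed by 4, against 80.5% without the block. For genes changed by 2 the shares were 11.1% and 31.2%. The simulated variances did not depend on signal or change, so these shares do not settle the cause either.

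The 6 arrays allow 10 splits into 3 and 3, too few for a share under 0.05. For genes, 1 of the 10 splits, the real one, gave at least 24, and the highest of the others gave 4; the other splits that part all 3 pairs gave 0 genes each. At an unadjusted p below 0.05 the real split gave 2000 genes and the other splits that part all 3 pairs 444, 210 and 312. The highest of all others was 2353, in a split that parts 1 pair. For lists, 3 of the 10 gave at least 10, the real one among them, and the highest of the others gave 13, a value reached by 2 splits that also part all 3 pairs.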
